A study of Drosophila melanogaster with 4 samples.

How the data were processed

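Wing imaginal discs, the larval epithelia that form the adult wing, were taken from third-instar Drosophila melanogaster. Per the labels' protocols, discs were dissociated in warm trypsin, filtered and passed to droplet-based 10x Genomics single-cell RNA sequencing. One driver, ap-Gal4, expressed GFP in all 4 genotypes, and in 3 of them it also expressed RNA interference constructs against subunits of the CDK8 kinase module. The genotypes were Control, Cdk8-CycC depletion, Med12 depletion and Cdk8-CycC-Med12 depletion, with 1 library each.

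Each library came with 1 table of the authors' own comparison of GFP-positive with GFP-negative cells of that library. Cell Ranger 3.0.2 and Seurat were used, per the submitters' processing notes. The Seurat version, the genome build and the filters on cells are not given in the sources used here, so no genome coordinates were printed. The treatment of doublets, droplets holding more than 1 cell, is not given either. A droplet with both a GFP-positive and a GFP-negative cell would count as GFP-positive and raise detection there. GFP was detected in 100% of GFP-positive and 0% of GFP-negative cells, and nub, a gene of the wing pouch, was detected in 100% of both sets in every table. The tables thus compare nub-expressing cells only.

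The authors' deposited fold is a natural log of the ratio between the mean expression of the cell sets, as the column name used in early Seurat releases implies. The file header does not state the base. If another base was used, every log2 value derived from these folds scales by one common factor, and the counts by size change with it. Log2 ratios of detection shares do not depend on that base. The deposited fold is taken to include a pseudocount of 1 added before the logarithm, as Seurat does, so it understates the difference of genes with low expression. The fold used here has no sign, and the sign was taken from the column that names the higher cell set. A signed fold was given as well, but it was blank for 853 genes of the combined depletion. The deposited detection values are the fraction of cells of each set in which a gene was found, printed here as percentages. The deposited p-value of each gene was computed by the authors over cells of 1 library, and every listed gene had a p-value below 0.01. These p-values treat cells as replicates and were not used here. Genes outside that limit were not listed, so an unlisted gene has no value, and genes listed in several tables are a selected subset. Numbers of cells and molecules per cell are not given in the sources used here. The depth is therefore unknown, and no interval was computed for a detection share.

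The deposited folds were converted to log2, with positive values for genes higher in GFP-positive cells. The log2 difference from control is the log2 fold of a depletion library minus that of the control library, over genes listed in both tables. With 1 library per genotype no test between genotypes was possible, and genes were called higher or lower by size alone, at a fold of at least 1.3 with detection in at least 10% of cells of one set. All 3 differences use the same control library, so a peculiarity of that library enters all of them.

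A set of 37 gene lists covering pathways, disc regions and cell types was written before the data were examined, as were the size rule, most of the alternatives and the rule for named genes. Under that rule the text names the targeted genes, ap and GFP, the 10 genes with the highest and the 10 with the lowest difference in each depletion, and the 5 at each end of the control library. It also names list members that passed the size rule or that illustrate a list's count, and genes past the size rule in all 3 depletions. The median difference of each list with at least 3 measured members was placed among 10000 random lists of the same size, matched on detection in 10 bins. Such a percentile describes these libraries and is not a p-value, because genes of a list are regulated together. The limits of 0.5 and 99.5 beyond which a list is said to stand apart were chosen after the data were seen. The direct comparisons of one depletion with another, which do not use the control, were added then too. Symbols were taken from the deposited tables, with older symbols looked up in a reference table of fly genes.

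Agreement between depletions was described by correlations across genes, with 100 simulations of unchanged libraries that share 1 control. Every library in these had equal normal noise, set from the smallest variance of the differences. The combined depletion was regressed on the sum of the single depletions, with 1000 resamples of genes. Simulations also gave the slope, the coefficients and, in 1000 repeats, the shared leading genes of unchanged libraries, all added after the data were seen. GFP is a transgene product, ap is the gene whose driver line was used, w marks many fly transgenes and Ubx was high in GFP-positive cells of the control. These 4 genes were left out together in an alternative, since their values need not be responses to the depletion, and the origin of w and Ubx transcripts is not given in the sources used here. Resampling genes does not measure the spread between libraries. The procedure was tested on simulated data built for the Cdk8-CycC comparison over 5073 genes, of which 200 were changed. It recovered 100% of genes changed by a log2 of 0.5 or of 1, and 0.5% of 200 unchanged lists stood apart. The simulated noise was normal with a log2 SD of 0.04, and unchanged lists were genes drawn at random. Both outcomes largely follow from that setting. The simulation held no spread between libraries and no joint regulation of genes, so it checks the calculation only. Alternatives changed the fold limit, the detection filter, centring, the measure, the subtraction of control, the treatment of unlisted genes, the matching of random lists and the set of genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.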

Results

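Single-cell transcriptomes of larval wing discs were compared in 4 genotypes, each with 1 library. The CDK8 kinase module is a dissociable part of the Mediator complex and consists of Cdk8, its partner Cyclin C (CycC), Med12 (encoded by kto in flies) and Med13 (encoded by skd). The series asked how separate module subunits affect cell proliferation and tissue size. Because ap-Gal4 acts in the dorsal compartment, GFP-positive cells are taken to carry the depletion and GFP-negative cells of the same disc are not. The sets differ in GFP detection, so a dorsal cell in which no GFP was found would count as GFP-negative. The authors' deposited tables listed 5524 genes for Control, 6799 for Cdk8-CycC depletion, 5568 for Med12 depletion and 6377 for the combined depletion. Cell numbers are unknown, and no value below has a replicate error.

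The targeted genes followed the labels, most clearly in the share of cells in which they were detected. In the authors' deposited table for the control, CycC (FBgn0004597) was detected in 43.2% of GFP-positive and 32.4% of GFP-negative cells. Under Cdk8-CycC depletion the shares were 18.9% and 32.2%, and under the combined depletion 32.8% and 48.0%. Cdk8 (FBgn0015618) was detected in 18.9% against 11.0% of cells in the control, 9.0% against 11.5% under Cdk8-CycC depletion and 16.8% against 21.5% under the combined depletion. The share for kto (FBgn0001324) was 38.6% against 28.6% in the control, 32.0% against 38.9% under Med12 depletion and 35.0% against 45.4% under the combined depletion. In libraries where a gene was not targeted, it was found in more GFP-positive cells, at 70.7% against 54.5% for CycC and 38.9% against 26.2% for Cdk8 under Med12 depletion, and at 44.7% against 29.1% for kto under Cdk8-CycC depletion. The log2 differences from control were small on the scale of mean expression, at -0.24 and -0.21 for CycC, -0.09 and -0.10 for Cdk8 and -0.14 and -0.20 for kto in the libraries that targeted them. None of these reached the 1.3-fold rule. The skd gene was not listed for the control, so its difference was not analysed here.

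**Figure D1:**
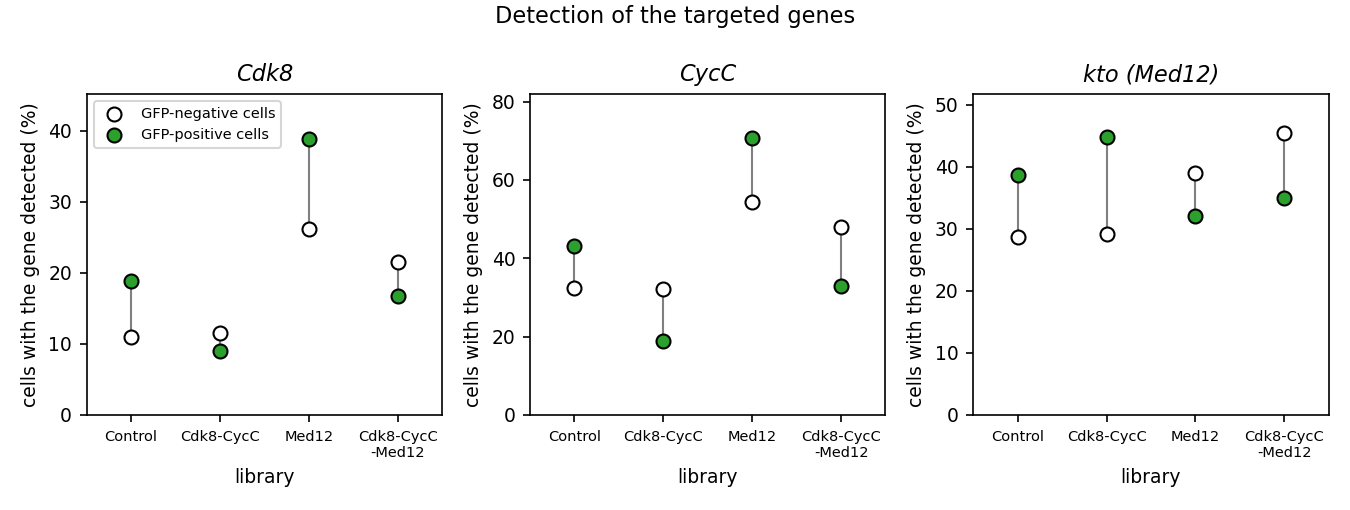
Percentage of GFP-positive (green) and GFP-negative (white) cells in which Cdk8, CycC and kto were detected, for each of the 4 libraries on the horizontal axis. GFP-positive cells lie above GFP-negative cells where the gene was not targeted and below where it was, for example 18.9% against 32.2% for CycC under Cdk8-CycC depletion.

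In the control library, 6 of 7 measured genes of the dorsal list were higher in GFP-positive cells, with a median log2 of 0.33. The dorsal selector gene ap was higher, at a log2 of 0.94, and was detected in 62.6% of GFP-positive and 5.3% of GFP-negative cells. GFP itself (4.90), Ubx (4.62), the eye colour gene w (1.71) and bnb (1.49) were the other genes at the top. The lowest were Gasp (-0.68), the ventrally expressed integrin gene if (-0.59), NetB (-0.40), the transcription factor gene vvl (-0.39) and frm (-0.38). By size, 16 genes were higher and 4 lower in the control, 25 and 10 under Cdk8-CycC depletion, 45 and 19 under Med12 depletion, and 27 and 26 under the combined depletion. Nearly all listed genes, 99.3% in the control and between 98.5% and 99.4% in the depletions, were detected in more GFP-positive than GFP-negative cells. The median log2 ratio of the detection shares was 0.49 in the control and 0.60, 0.42 and 0.48 in Cdk8-CycC, Med12 and combined depletion. More GFP-positive cells were also counted for 98.7% of the control genes whose mean was higher in GFP-negative cells, so detection shares and mean expression often pointed in different directions. Judged by the ratio of detection shares, 3597 genes were higher and 1 lower in the control, 4481 and 4 under Cdk8-CycC depletion, 2857 and 12 under Med12 depletion and 3588 and 5 under the combined depletion. With that ratio centred on its median, the counts were 145 and 214, 320 and 744, 298 and 227, and 438 and 376.

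Under Cdk8-CycC depletion, genes of the cell cycle were higher in GFP-positive cells relative to control. Of 42 measured genes of the G1-S and DNA replication list, 39 lay above 0, with a median log2 difference of 0.14 against 0.03 for matched random lists (percentile 100). Examples were the helicase subunits Mcm7 (0.39) and Mcm3 (0.33), the replication clamp PCNA (0.36) and RnrL (0.33), which encodes the large subunit of ribonucleotide reductase. All 34 measured genes of the G2-M list lay above 0, with a median of 0.12 (percentile 100), led by stg (0.52), which encodes the Cdc25 phosphatase that triggers mitosis. Only Mcm7 and stg passed the size rule among these lists, so the shifts were small per gene and shared by many genes. Both lists also stood apart by detection share. The remaining genes among the 10 highest were wbl (0.37), Cpr12A (0.34), the aldo-keto reductase gene Akr1B (0.33), Mink (0.32) and the histone variant gene His2Av (0.31).

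Over 5073 genes compared, 2 were higher and 4 lower by size in that depletion, and the central 95% of genes lay between -0.07 and 0.15. The split was 1 higher and 4 lower after centring on the median of all genes, 249 and 24 by detection share, and 95 and 58 by the centred detection share. The 4 lower genes by mean expression were GFP (-0.95), Ubx (-0.76) and the heat shock genes Hsp68 (-0.65) and Hsp26 (-0.43). Among 7 measured heat shock genes, 6 lay below 0, with a median of -0.20 (percentile 0). By detection share the list lay at percentile 64.1, on the other side of the middle, but 4 of the 7 were detected in over 95% of both cell sets and had little room to vary on that measure. Without GFP, w, Ubx and ap, 2 genes were higher and 2 lower. The other genes among the 10 lowest were ImpE2 (-0.32), w (-0.30), Hsp27 (-0.30), CG3097 (-0.28), CG9691 (-0.26) and CycC. All 11 measured genes of EGFR signalling lay above 0, with a median of 0.06 (percentile 98.8), short of the limit of 99.5. The oxidative phosphorylation list had 29 of 30 members above 0 and lay at percentile 99.3, also short of it.

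Under Med12 depletion the genes of largest difference lay outside the cell cycle lists. Of 4473 genes compared, 12 were higher and 5 lower, and the central 95% lay between -0.08 and 0.15. By detection share the split was 46 higher and 87 lower, and 72 and 46 after centring that share. The highest were CG15282 (1.86), CG7322 (1.32), grass (0.77), which encodes a serine protease, w (0.71), Vajk2 (0.64), CG14984 (0.55), GstD3 (0.43), Vajk3 (0.43), CG7675 (0.42) and CG11438 (0.41). The small heat shock gene Hsp23 (0.38) also passed the size rule. The 5 lower genes were robo2 (-0.51), which encodes an axon guidance receptor, scyl (-0.46), GFP (-0.45), the integrin gene mew (-0.45) and vvl (-0.42). The next lowest were chrb (-0.36), olf413 (-0.32), E(spl)m7-HLH (-0.29), hoip (-0.28) and wg (-0.26). Both scyl and chrb encode inhibitors of TOR signalling, and wg encodes the Wingless ligand.

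All 8 measured glycolysis genes lay above 0 under Med12 depletion, with a median of 0.11, led by Eno (0.34) and Gapdh1 (0.32). That list lay at percentile 99.5, on the limit and not past it. The lipid synthesis list had 7 of 7 members above 0 with a median of 0.07 (percentile 99.8), FASN1 (0.12) being the highest, but it lay at percentile 84.7 without subtraction of the control and at 97.8 by detection share. Ribosome biogenesis and growth genes went the other way, with 6 of 6 below 0 and a median of -0.14, including mod (-0.22) and Myc (-0.08), but by detection share the list lay at percentile 60.5, on the other side. The G1-S and DNA replication list did not stand apart, with 22 of 35 members above 0 and a median of 0.01 (percentile 7.48). In the direct comparison of Cdk8-CycC with Med12 depletion, 34 of 36 members were higher in the former (median 0.10, percentile 100). Glycolysis was lower there in 6 of 7 members (median -0.31, percentile 0). By size, 6 genes were higher and 15 lower among 5040 in that comparison.

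Of 4835 genes compared under the combined depletion, 10 were higher and 10 lower by size. Among the 4261 genes also measured under Med12 depletion these were 10 and 6, of which 8 and 5 passed the size rule in the same direction there. By detection share the split was 113 higher and 33 lower, and 124 and 27 after centring. The higher genes were CG15282 (1.84), CG7322 (0.74), w (0.73), Vajk2 (0.54), Hsp23 (0.51), CG14984 (0.51), CG7675 (0.44), Msp300 (0.44), GstD3 (0.41) and the chitinase gene Cht10 (0.38). The lower genes were zfh2 (-0.67), a hinge gene, vvl (-0.64), GFP (-0.62), scyl (-0.56), robo2 (-0.55), mamo (-0.48), the Wingless feedback inhibitor gene nkd (-0.48), Phk-3 (-0.39), mew (-0.38) and the Notch target E(spl)m4-BFM (-0.38). All 8 measured glycolysis genes (median 0.10, percentile 99.7) and all 8 lipid synthesis genes (median 0.07, percentile 99.6) lay above 0. The lipid synthesis list fell short of the limit without subtraction of the control (99.1), with the mean over members (98.98) and among unmatched lists (99.4). Of 4 measured heat shock genes, 3 lay above 0 (median 0.14, percentile 99.9), with percentile 49.8 by detection share. The 4 values ran from -0.12 to 0.51, and the median depends on Hsc70-3 (0.26), which acts in the endoplasmic reticulum. Only Hsp23 and Hsc70-3 among the 4 genes were also measured relative to control under Cdk8-CycC depletion. Hsp23 lay at -0.20 there, and Hsc70-3, at 0.23, was higher as in the combined depletion (0.26).

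Replication genes under the combined depletion were intermediate, with 37 of 41 above 0 and a median of 0.06 (percentile 99.9), which moved to percentile 78.9 by detection share. Compared directly with Cdk8-CycC depletion, 41 of 45 replication genes and 32 of 35 G2-M genes were lower in the combined depletion, with medians of -0.09 and -0.07 (percentile 0 for both). Compared directly with Med12 depletion, 30 of 36 replication genes were higher in the combined depletion (median 0.04, percentile 100). The G2-M list did not stand apart from control there (median 0.03, percentile 79.1).

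Ribosomal protein genes were lower in GFP-positive cells of every depletion relative to control, with 39 of 40 members below 0 each time and medians of -0.12, -0.10 and -0.12 for Cdk8-CycC, Med12 and combined depletion (percentile 0 for each), whereas by detection share the list lay at percentiles 96.5, 100 and 100, on the other side. These genes were detected in nearly every cell, so their detection share had little room to vary. No member passed the size rule. Within the libraries, 21 of 41 listed ribosomal protein genes were lower in GFP-positive cells of the control, against 78 of 83, 76 of 78 and 75 of 78 in the depletions.

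The Wingless signalling and hinge lists had small negative medians relative to control in all 3 depletions, which did not hold under every alternative. The Wingless list had medians of -0.05, -0.17 and -0.08 (percentile 0 each), from 10, 7 and 6 measured members, of which 6, 5 and 4 lay below 0. Its members went both ways in each depletion, as under Med12 depletion, where Wnt6 lay at -0.21 and vg at 0.21. By detection share the list no longer stood apart under Med12 (percentile 8.38) or combined depletion (10.6), and with unlisted genes set to 0 it did not under Cdk8-CycC depletion (10.7). The hinge list had medians of -0.10, -0.07 and -0.10 (percentiles 0, 0.01 and 0), with 5 of 5, 4 of 4 and 4 of 5 members below 0. Without subtraction of the control, the hinge list lay at percentiles 40.3, 100 and 88.1, on the other side of the middle for Med12 and combined depletion, and by detection share it lay at 6.38 under Med12 depletion. The notum list stood below in Med12 (median -0.11) and combined depletion (-0.09), the dorsal list in Med12 depletion (-0.06) and the pouch list in the combined depletion (-0.16, 3 members), but the dorsal list lay at percentile 52.2 by detection share and 100 without subtraction of the control, the pouch list at 99.9 by detection share, and the notum list without subtraction of the control at 99.9 in the combined depletion. Under Med12 depletion the notum list no longer stood apart by detection share (percentile 1.71) or without subtraction of the control (4.28). The dorsal, hinge and notum lists were already higher in GFP-positive cells of the control (medians 0.33, 0.13 and 0.13). Their positions without subtraction carry that difference and say little about the shift from control. The Notch list stood below under Cdk8-CycC (median -0.02, mean 0.00) and Med12 depletion (median -0.05), but lay at percentile 52.8 without subtraction of the control in the former and at 98.8 by detection share in the latter.

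Among the remaining lists that stood apart, sensory organ precursor genes were below under Cdk8-CycC depletion (median -0.06, 5 members, but percentile 16.5 by detection share) and TOR and insulin genes under Med12 depletion (median -0.02, percentile 0.40), the latter moving to 50.3 by detection share. The list of module subunits stood below under Cdk8-CycC and the combined depletion, and contains the targeted genes. In all, 28 of 92 list comparisons over 32 lists stood apart, 7 above and 21 below, where 0.92 would be counted by chance if genes were independent. For differences from control, histone, hemocyte, myoblast, peripodial and anterior compartment lists had at most 2 measured members and were not placed among random lists. Compared directly with Cdk8-CycC depletion, 3 of 4 myoblast genes were lower in the combined depletion (median -0.09, percentile 0.08). Of 3 peripodial genes, 2 were higher there (median 0.11, percentile 99.8), led by Ubx (0.65), whose origin is not given. With so few members, these positions do not show a shift in cell types.

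**Figure D2:**
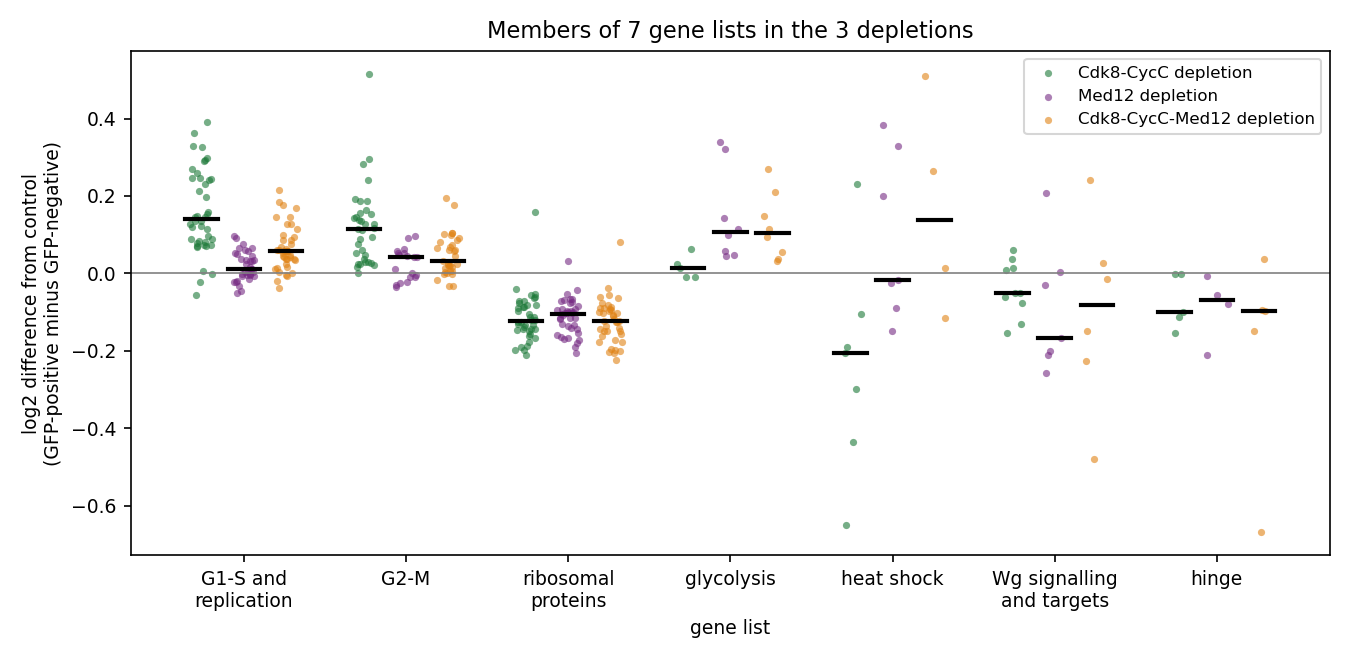
Log2 difference from control (vertical axis) of each measured member of 7 gene lists (horizontal axis) under Cdk8-CycC (green), Med12 (purple) and combined depletion (orange), with black bars at the medians. Replication and G2-M genes sit highest under Cdk8-CycC depletion (medians 0.14 and 0.12), and ribosomal protein genes sit near -0.12, -0.10 and -0.12. By detection share, ribosomal protein genes in all 3 depletions and heat shock genes in Cdk8-CycC and combined depletion lay on the other side of the middle, though ribosomal protein genes and 4 of 7 heat shock genes under Cdk8-CycC depletion were detected in nearly every cell, and hinge genes in Med12 and combined depletion did so without subtraction of the control.

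The depletions were then compared across genes, which are not independent replicates. Differences from control had a Pearson r of 0.80 and a Spearman rho of 0.61 between Med12 and the combined depletion, 0.47 and 0.54 between Cdk8-CycC and the combined depletion, and 0.34 and 0.43 between Cdk8-CycC and Med12 depletion. Simulated unchanged libraries sharing 1 control gave 0.50 and 0.48. The covariance was 0.00403, 0.00189 and 0.00142 for these pairs, against 0.00161 in the simulation. The simulation treated the smallest observed variance of the differences as noise, split equally between control and depletion library. The simulated covariance follows from that setting, and the control's own noise is unknown with 1 library. By covariance the Cdk8-CycC and Med12 pair did not exceed this assumed value. That pair had the same direction in 72.4% of genes, against 66.5% in the simulation. The simulation was centred on 0, whereas the measured medians lay above 0 (0.03 for Cdk8-CycC and 0.02 for Med12 depletion). For Cdk8-CycC and combined depletion, Pearson r did not exceed the simulation, while rho and the covariance did. Part of any excess may come from the shared control, which could not be split there. Within libraries, with no control subtracted and without GFP, w, Ubx and ap, Pearson r was 0.88 between Med12 and combined depletion. It was 0.66 for Cdk8-CycC with Med12 and 0.67 for Cdk8-CycC with combined depletion. Control with Cdk8-CycC, Med12 and combined depletion gave 0.70, 0.67 and 0.60. By size, Med12 and the combined depletion shared 8 higher genes, from 12 and 10, and 5 lower genes, from 5 and 6, which were GFP, mew, robo2, scyl and vvl. Of 1000 simulations of unchanged libraries sharing 1 control, none with normal noise shared more than 4 higher genes. With noise drawn from the combined minus Med12 differences, which has longer tails, the mean was 5.29 and the highest 10. Those differences compare 2 depleted genotypes and were one-sided, with 0 genes higher and 3 lower by size. A low value drawn for the shared control makes shared higher genes, so this simulation cannot decide about the 8. For lower genes neither simulation gave more than 3, but for the second this follows from the side on which its noise had the tail. Without the control, 7 of the 8 higher and 2 of the 5 lower genes passed the size rule within both libraries. Of these, w (1.71) and CG7322 (0.63) were also past it as higher in the control, and vvl (-0.39) as lower. GFP (4.90) and mew (0.50) were high in the control and thus unlikely to pass as lower. Such counts are not free of the difference between the cell sets that exists without depletion. Cdk8-CycC and Med12 depletion shared GFP as a lower gene and no higher one, but Cdk8-CycC depletion had only 1 higher gene among those measured in both. At a fold of 1.2 they shared 4 higher genes (CG14984, GstD3, Msp300 and wbl) from 20 and 36. The shared control raises such overlaps. The Med12 and combined libraries were also alike in GFP-negative cells, which are taken to carry no depletion. Over 4300 genes, the median share of these cells was 36.7% and 35.0% there, against 22.4% in the control and 24.5% under Cdk8-CycC depletion. Agreement through the depletion and through other properties shared by those libraries cannot be told apart. Over 4150 genes listed in all 4 tables and past the 10% detection filter in each comparison, 0 were higher and 1, GFP, was lower by the size rule in all 3 depletions.

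The combined depletion was also set against the sum of the single depletions. Across the same 4150 genes it followed the sum with a slope of 0.53 (0.47 to 0.60 over resampled genes) and a Pearson r of 0.79. Simulated unchanged libraries sharing 1 control gave a slope of 0.33 and an r of 0.58, and noise in the sum lowers the slope of an additive response, so neither addition nor a departure from it could be shown. With both depletions as separate terms, the coefficients were 0.70 for Med12 and 0.27 for Cdk8-CycC, against 0.33 for each in the simulation. The Med12 and combined libraries were also alike in detection in GFP-negative cells, so the larger coefficient need not reflect the depletion. CG15282 (0.08, 1.86 and 1.84 in Cdk8-CycC, Med12 and combined depletion) followed Med12 depletion, and CG7322 (0.03, 1.32 and 0.74) and grass (0.00, 0.77 and 0.31) lay between. PCNA (0.36, -0.04 and 0.12) and Mcm3 (0.33, -0.03 and 0.08) lay between as well. The Med12 and combined libraries also differed in GFP-negative cells. Eip78C was detected in 61.9% and 31.4% of them and ImpE3 in 59.1% and 27.2%. Eip74EF (44.3% and 54.1%) and ftz-f1 (47.4% and 71.7%) went the other way. Differences in size between these depletions may therefore come from the libraries, which was not tested.

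**Figure D3:**
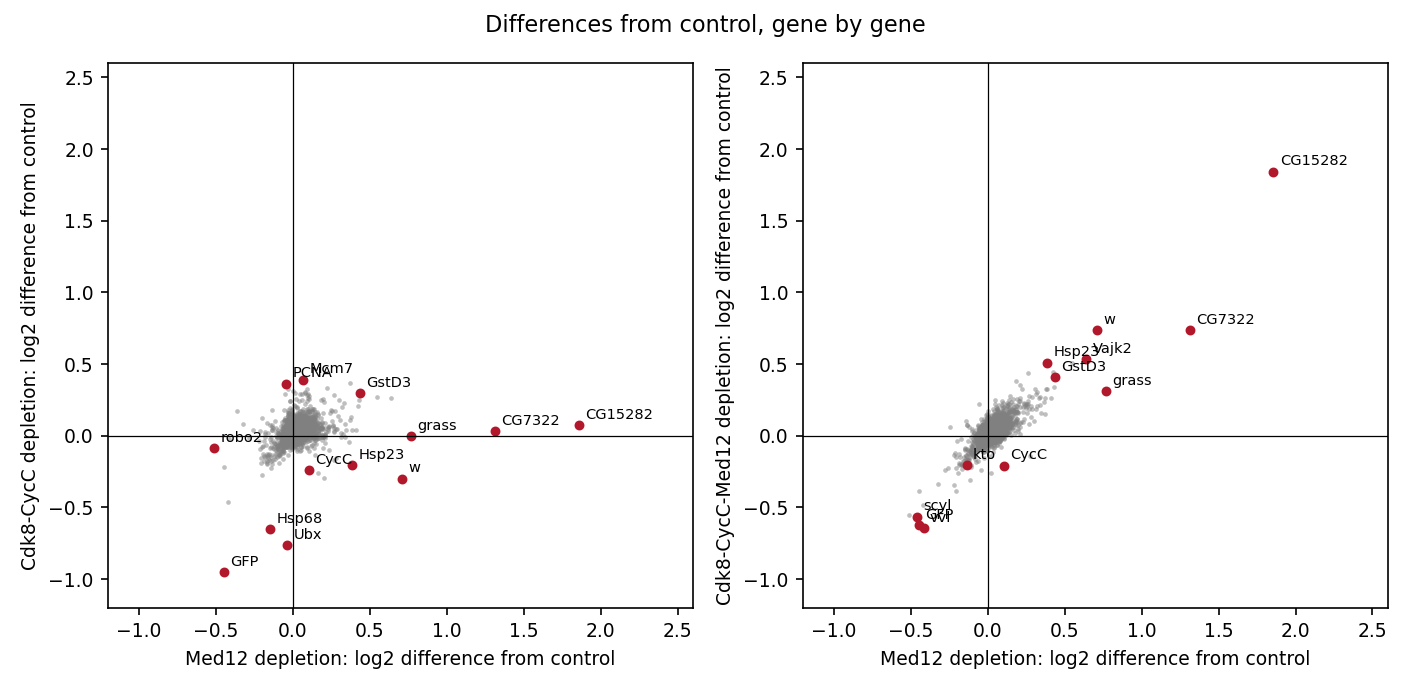
Log2 difference from control of each gene (dots, selected genes in red) under Med12 depletion (horizontal axis) against Cdk8-CycC depletion (left) and the combined depletion (right). The right panel is the tighter one, with a Pearson r of 0.80 against 0.34, and CG15282 lies at 1.86 and 1.84 there. The Med12 and combined libraries were also alike in detection in GFP-negative cells.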

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

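All tests in this part were chosen after the results were seen. The heat shock list had a median log2 difference from control of -0.20 under Cdk8-CycC depletion and 0.14 under the combined depletion. These medians come from largely different genes, since only 2 members were measured in both, of which Hsp23 changed direction (-0.20 and 0.51) and Hsc70-3 did not (0.23 and 0.26). The median under combined depletion comes from 4 genes and depends on Hsc70-3, which acts in the endoplasmic reticulum. The difference between the depletions was not tested against replicates, since there are none. The direct comparison, which uses the same genes on both sides, placed 5 of 6 measured heat shock genes higher in the combined depletion, with a median of 0.12 (percentile 100). Heat or handling that differed between whole libraries would also act on GFP-negative cells. Among the 4 heat shock genes listed in both tables and detected in under 95% of these cells, detection moved by a median of -3.7 percentage points from Cdk8-CycC to combined depletion, between -6.6 for Hsp70Ab and 17.6 for Hsc70-5. Libraries did differ in GFP-negative cells, as Hsp68 was detected in 80.4% of them in the control, 81.3% under Cdk8-CycC depletion and 48.1% under Med12 depletion, and Hsp70Bc in 79.8% under Cdk8-CycC and 41.2% under Med12 depletion. Over 4300 genes listed in all tables, with no detection filter, the median share of these cells was 22.4% in the control, 24.5% under Cdk8-CycC, 36.7% under Med12 and 35.0% under combined depletion. The median of -3.7 points for heat shock genes thus stood against a general rise from Cdk8-CycC to combined depletion. With 4 genes that moved apart and 1 library each, handling and an effect of the depletion cannot be told apart.

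The eye colour gene w also went opposite ways, at -0.30 under Cdk8-CycC depletion and at 0.71 and 0.73 under Med12 and combined depletion. This difference was not tested. The gene w marks many fly transgenes, and the insertions carried by each genotype are not given in the sources used here, so a difference in transgenes stays open.

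Replication genes were higher in GFP-positive cells under Cdk8-CycC depletion. If deeper sampling of GFP-positive cells were the source, the list's detection shares would move like those of genes with matched detection, but the list lay at percentile 100 among them. If the source were a peculiarity of the control library, the list would not stand apart where the control is not used, but it lay at percentile 100 in Cdk8-CycC minus Med12 depletion. Both results argue against these explanations. A peculiarity of the single Cdk8-CycC library stays open, as does an effect of the depletion on proliferation, which remains a hypothesis.

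Ribosomal protein genes were lower in GFP-positive cells of the 3 depletion libraries. A few abundant transcripts diluting all others would also lower other genes detected in at least 99% of both cell sets. These had a median log2 of 0.053 under Cdk8-CycC depletion, 0.063 under Med12 and 0.075 under the combined depletion (28, 20 and 24 genes). Heat shock and mitochondrially encoded genes had been left out of that set. Among genes left out and found in at least 99% of both sets, Hsp26 (-0.63), Hsp27 (-0.43), Hsp23 (-0.38) and Hsp83 (-0.35) were lower under Cdk8-CycC depletion. Under Med12 depletion Hsp23 (0.21) and Hsp27 (0.06) were higher. The genes kept were not lower as a group, but the result depends on which genes are kept, so it does not decide about dilution. In the control the median of the genes kept was -0.10 over 15 genes. Relative to control the genes kept thus went the opposite way to ribosomal protein genes. The genes listed differ between libraries, and a peculiarity of the control library stays open. Deeper sampling of GFP-positive cells would be expected to act in the control too, where 51.2% of listed ribosomal protein genes were lower. Under Cdk8-CycC depletion the detection gap was wider than in the control (median log2 detection ratios 0.60 and 0.49). Under Med12 and combined depletion it was narrower (0.42 and 0.48), yet 97.4% and 96.2% of listed ribosomal protein genes were lower, which goes against deeper sampling there. As the spread between control libraries is unknown with only 1, deeper sampling and an effect of the depletions cannot be told apart. The difference from control rests on that 1 library in all 3 depletions.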

How the results depend on the processing

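No paired analysis was possible because each genotype had 1 library. Depth is unknown, and the genes listed are a selected set. The centred detection ratio, the value of 0 for unlisted genes in gene lists, and leaving out GFP, w, Ubx and ap were chosen after the data were seen. So were the yardsticks for a moved correlation, slope or targeted gene, which used resampled genes or the spread over genes in place of replicates. Of 124 alternative gene counts, 60 stayed within 1.5 times the main count. Of 644 alternative list percentiles, 568 stayed on the same side of the limits, 30 fell back within them, 31 newly passed one and 15 changed direction. Centring cannot move a list's percentile. The cause was not tested for any change given here. Values below are in the order control where included, Cdk8-CycC, Med12 and combined depletion.

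At a fold of at least 1.2, 36, 69, 93 and 84 genes were higher and 19, 29, 44 and 42 lower within libraries, and relative to control 25, 36 and 26 were higher and 8, 9 and 15 lower. At a fold of at least 1.5, 11, 9, 17 and 12 were higher and 2, 4, 3 and 3 lower within libraries, and relative to control 0, 5 and 3 were higher and 3, 0 and 3 lower. Stricter and looser limits change counts by construction. Centred folds gave 1 higher gene in place of 2 under Cdk8-CycC depletion. Without ribosomal protein, mitochondrially encoded and heat shock genes, 6 genes were lower within the Cdk8-CycC library and 2 relative to control. With unlisted genes at 0, 7, 17 and 23 genes were lower than in control. Without subtraction of the control, but only over genes also listed for the control, 25, 44 and 27 were higher and 8, 9 and 14 lower.

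By detection ratio, 3597, 4481, 2857 and 3588 genes were higher and 1, 4, 12 and 5 lower within libraries, and relative to control 249, 46 and 113 were higher and 24, 87 and 33 lower. Centring that ratio gave 145, 320, 298 and 438 higher and 214, 744, 227 and 376 lower within libraries, and 95, 72 and 124 higher and 58, 46 and 27 lower than in control. The targeted genes moved on this scale to -1.13, -0.21 and -1.14 for Cdk8, -1.18, -0.040 and -0.96 for CycC, and 0.19, -0.71 and -0.81 for kto. The slope on the sum was 0.43.

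Directions that changed by detection ratio were those of ribosomal proteins (percentiles 96.5, 100 and 100), heat shock under Cdk8-CycC (64.1) and combined depletion (49.8), pouch under the combined depletion (99.9), and under Med12 depletion dorsal (52.2), Notch (98.8), growth (60.5) and TOR and insulin genes (50.3). Lists that fell back within the limits were Notch (30.8) and sensory organ precursor (16.5) under Cdk8-CycC depletion, Wingless (8.38), hinge (6.38), notum (1.71) and lipid synthesis (97.8) under Med12 depletion, and Wingless (10.6) and G1-S genes (78.9) under the combined depletion. Lipid synthesis (99.9), notum (0.36) and posterior compartment (0.44) newly passed a limit under Cdk8-CycC depletion.

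Without subtraction of the control, direction changed for dorsal (100) and hinge genes (100) under Med12 depletion, Notch (52.8) under Cdk8-CycC depletion, and hinge (88.1) and notum (99.9) under the combined depletion. Dorsal, hinge and notum genes were already higher in GFP-positive cells of the control, which shapes these positions. Wingless (3.21) and hinge (40.3) under Cdk8-CycC, TOR and insulin (8.34), lipid synthesis (84.7) and notum (4.28) under Med12, and heat shock (99.2) and lipid synthesis (99.1) under the combined depletion fell back. Newly past a limit under Cdk8-CycC depletion were dorsal (100), Dpp (0.13), EGFR (99.8), JNK (0.14), oxidative phosphorylation (99.8), mitochondrially encoded (0), notum (100) and pouch genes (0.01). The dorsal and notum lists had been below the middle there (1.47 and 5.42). Under Med12 depletion these were glycolysis (100) and mitochondrially encoded genes (0.04), and under the combined depletion dorsal (100), Hh (99.7) and cuticle genes (99.9).

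With unlisted genes at 0, Wingless under Cdk8-CycC (10.7), TOR and insulin (1.58) and lipid synthesis (97.53) under Med12, and pouch (9.07) under the combined depletion fell back. Newly past a limit were glycolysis (0.11) and oxidative phosphorylation (99.96) under Cdk8-CycC, glycolysis (99.6), mitochondrially encoded (100, from 1.66) and sensory organ precursor (0.47) under Med12, and ecdysone (99.9), cuticle (99.7) and sensory organ precursor (0.04) under the combined depletion. With the mean over members, Notch under Cdk8-CycC (2.97), TOR and insulin (9.50) and lipid synthesis (96.6) under Med12, and G1-S (99.4), lipid synthesis (98.98), notum (1.2) and pouch (4.54) under the combined depletion fell back, while Notch under the combined (0.09) and glycolysis under Med12 depletion (99.9) newly passed. Among 2000 unmatched lists, TOR and insulin (0.8) and lipid synthesis (98.8) under Med12 and lipid synthesis (99.4) under the combined depletion fell back. Growth under the combined depletion (0.05), glycolysis (100) and mitochondrially encoded genes (0.05) under Med12, and oxidative phosphorylation under Cdk8-CycC depletion (100) newly passed. Without a detection filter, glycolysis under Med12 depletion moved just past the limit (99.53) and notum under the combined depletion fell back (0.57).

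Spearman's rho between Cdk8-CycC and Med12 depletion was 0.41 with detection of at least 25%, 0.46 by detection ratio and 0.49 without subtraction of the control. Between Med12 and the combined depletion it was 0.70 by detection ratio and 0.57 without subtraction. The remaining alternatives of these correlations, the slope and the targeted genes changed neither direction nor size beyond those yardsticks.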

Other observations

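Both tests in this part, and the gene families they use, were chosen after the named genes had been seen. The genes Hsc70-3 and wbl act in the endoplasmic reticulum, where secreted proteins fold, and had positive differences from control that did not reach the 1.3-fold rule. The chaperone gene Hsc70-3 lay at 0.23, 0.33 and 0.26 under Cdk8-CycC, Med12 and combined depletion, and wbl at 0.37, 0.37 and 0.26. A hypothesis is that folding genes as a family rise under Med12 depletion. Without these genes and Spp, 20 of 22 members lay above 0 there, with a median of 0.12 (percentile 100), examples being Pdi (0.20), Calr (0.20) and CaBP1 (0.17). Under the combined depletion 22 of 23 lay above 0 (median 0.07, percentile 99.9), and under Cdk8-CycC depletion 20 of 24 (median 0.04, percentile 78.4). These values are consistent with the hypothesis under Med12 depletion, but by detection share the family did not stand apart, at percentiles 26.3, 77.3 and 93.3 for Cdk8-CycC, Med12 and combined depletion, the first on the other side of the middle.

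GstD3, a glutathione S-transferase gene, was 1 of 3 genes higher in all 3 depletions at a fold of 1.2, with values of 0.30, 0.43 and 0.41. The others were CG14984 (0.27, 0.55 and 0.51) and the nuclear envelope gene Msp300 (0.28, 0.26 and 0.44). Within libraries Msp300 lay at -0.19 in the control and at 0.09, 0.07 and 0.24 in the depletions. No depletion library alone reached a fold of 1.2 for Msp300, so its place rests largely on the low control value. A hypothesis of a rise shared by the glutathione S-transferase family was not decided. Without GstD3, GstT3 and GstD1, 7 of 9 members lay above 0 under Med12 depletion, with a median of 0.04 (percentile 85.8, 88.0 by detection share and 99.99 without subtraction of the control). The percentile was 86.7 under Cdk8-CycC and 97.7 under combined depletion, or 91.7 and 98.8 without subtraction.

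Mitochondrially encoded genes were lower in GFP-positive cells in 12 of 12 listed genes of the control (median log2 -0.18) and 8 of 8 under Cdk8-CycC depletion (-0.20). Only 3 and 2 were listed under Med12 and combined depletion, with medians of -0.29 and -0.016, too few to describe the group there. The deposited table of the combined depletion left the signed fold blank for 853 genes, whose sign was read from the named cell set.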
